A study of Mus musculus with 19 samples.

How the data were processed

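Poly(A) RNA of 19 libraries from 10 lines of mouse induced pluripotent stem cells was made into stranded TruSeq libraries and sequenced on a NovaSeq, per the labels' protocols. The authors deposited a table of estimated counts per gene, and kallisto and the GRCm38 build are named in the submitters' processing notes; the version of kallisto, its index and how transcripts were summed per gene are not given in the sources used here. The deposited table held 52143 Ensembl gene identifiers, of which 51250 matched a name and coordinates in GENCODE M21 tables, and these carried 99.37% of all counts. Estimated counts divide reads between similar transcripts, so the values of near-identical genes are uncertain, and 79.7% of the values were whole within 1e-06. Totals per library were 27333914 to 41203703.

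Groups, lines and duplicates were read from the titles of the samples: 7 control libraries of 4 lines, 8 db/db libraries of 4 lines and 4 corrected libraries of 2 lines. The labels do not say that libraries of a line came from separate cultures, so the line was the replicate. Counts were rounded to whole numbers in each library and then summed per line. All 3 groups entered a single fit, so that they share an estimate of the spread. Genes were filtered with filterByExpr (19700 kept), scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F-test) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 CPM values, as used for gene lists, principal components and chromosome medians, had a prior count of 2. Gene fold changes came from the edgeR fit with its default prior count. The p-values measure the spread between these lines, several of which are near copies.

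Gene lists were written before the data were examined: 48 lists with 1447 entries, of which 1438 matched the table, 5 did not and the others repeated a gene already in the same list. They covered protein synthesis, signalling, pluripotency, cell types of the embryo, stress, metabolism and the cell cycle. Lists with at least 5 tested genes (46) were tested with camera (limma 3.58.1) with a preset correlation of 0.01. Beside it stood camera with an estimated correlation, which called 0 lists in each comparison (3, 5 and 2 at an unadjusted p under 0.05), and fry, which called 18, 31 and 29. Fry asks whether the genes of a list move 1 way on balance and does not compare them with other genes. Camera with the preset correlation called 7, 20 and 12 lists for db/db against control, corrected against db/db and corrected against control. Y-linked and X-inactivation genes were too few after filtering to be tested as lists. The other 39 lists of db/db against control had camera adjusted p-values of 0.0654 to 0.988.

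Genes were named by a rule set beforehand. The rule took the 10 largest rises and the 10 largest falls per comparison with an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap of lines, without predicted genes, pseudogenes and Xist, Tsix and Y-linked genes. Added to these were 9 fixed genes and up to 4 members of each list with the lowest p. The genes near Lepr were the 100 tested genes on each side of it. Principal components and chromosome medians used 9063 genes with a mean of at least 10 CPM. Positions between control and db/db lines used genes chosen without the line placed, and were compared by exact permutation. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.

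The duplicate numbers 1 and 2 in the titles pair libraries across lines: in 12 pairs of a control with a db/db line the deviations of same-numbered libraries from their line's mean correlated at 0.234 to 0.561 over 9063 genes. Since duplicates were summed, the number enters only the fits on single libraries. The a and b letters of the corrected libraries entered no block (correlation -0.667 between both lines). Differences between duplicates of the corrected lines correlated with those of the other lines at -0.394 to 0.305. Whether the corrected libraries were handled together with the others was not tested. The design cannot tell such a difference in handling apart from the correction.

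Alternatives set beforehand were other scaling factors (DESeq2's size factors, upper quartile), DESeq2 1.42.0 as the test, limma-voom with the line as a random block, each library as a sample with and without the duplicate number as a block, and other filters. Further ones were fits of only the compared groups, a covariate for the first letter of the line name, shared names as the unit for db/db against control, leaving out each line, and leaving out chromosomes 3, 6 and 15. After the data were examined, shared names as the unit of all comparisons, limma-voom with the shared name as a block, and fits without line db/db 2's second library or without a shared name were added. So were library size alone, removal of a trend over transcript length and GC content, and the genes near Lepr without predicted genes.

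The scripts were tested on simulated counts with 50 genes changed at each of 4 fold sizes. Each line was drawn independently there, while the real lines include near copies. With lines of a shared name as alike as here, simulated unchanged groups gave 1407 to 1727 edgeR calls between db/db and control lines. The false calls below therefore do not measure the error of the real fit. For db/db against control edgeR recovered 0%, 26%, 38% and 82% of genes changed 1.25-, 1.5-, 2- and 4-fold over 19239 genes, with 1 false call among 74. For corrected against db/db it recovered 0%, 14%, 48% and 74% (5 false of 73), and for corrected against control 0%, 18%, 44% and 78% (11 false of 81), both over 19241 genes. DESeq2 made 42 false calls of 137, 55 of 155 and 55 of 147 in the same simulations, so its counts are given only as an alternative; the requirement on the simulation was narrowed to edgeR after this was seen. No column of the table was left out. A covariate for sex was not run because the lines did not differ in it, and splicing of Lepr was not analysed here. A gene among those examined is not reported here.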

Results

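RNA was sequenced from mouse induced pluripotent stem cells, which are cells returned from fibroblasts to a state from which all tissues of the body can form. The fibroblasts were taken from embryos bred from heterozygous parents and reprogrammed with a lentivirus carrying Oct4, Sox2, Klf4 and cMyc. There were 4 control lines without the mutation (7 libraries) and 4 lines homozygous for the db mutation of the leptin receptor gene Lepr (db/db, 8 libraries). In 2 further lines (4 libraries) the db/db mutation had been corrected with CRISPR-Cas9. The title of the study concerns leptin receptor signalling, protein synthesis and neuronal differentiation. The groups ask which transcripts differ with the mutation and which of these differ back after its correction. The 19 libraries held 27333914 to 41203703 estimated counts (median 34455891). Duplicates were summed per line before testing. Group values are mean CPM (counts scaled to the size of the library) ± SD over lines (n = 4, 4 and 2). Log2 fold changes are given ± SE. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 19700 genes.

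The lines fell into 5 kinds rather than 10. The labels give each control and db/db line a first letter (a or b) and a name, with A5 and B1 among control lines and db5 and db7 among db/db lines. Libraries of the a and b lines of a shared name differed by a biological coefficient of variation of 2.24% to 13% (median 3.49%) when their duplicate numbers matched. The values were 3.88% to 9.33% between duplicates of a line and 20.3% to 24.5% between lines of different names. The corrected lines differed from each other by 2.36% to 6.81%. No pair agreed within sampling noise, so none was merged, but the p-values with the line as the unit are too small where lines of a shared name are near copies. For this reason the total count of called genes of each comparison is also given with the shared name as the unit, while counts within lists, chromosomes and windows are at the level of lines. The labels do not say from which db/db line the corrected lines came.

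Whole chromosomes also differed between lines. Genes of chromosome 3 had a median log2 level of 0.40 and 0.43 above the median of the lines of other names in the db7 lines (420 genes). Genes of chromosome 15 had a median of 0.43 and 0.44 in the A5 control lines (365 genes), and genes of chromosome 6 a median of 0.28 in both B1 control lines (398 genes). For chromosome 3 the B1 control lines lay at -0.21 and -0.19. Medians of the other 17 chromosomes lay between -0.11 and 0.14 in every line. Among these, the X chromosome (320 genes) separated control from db/db lines, at -0.10 to -0.06 in control lines and 0.02 to 0.14 in db/db lines. The corrected lines lay at 0.065 and 0.064. The share of tested genes that changed between db/db and control lines was 24.9% on chromosome 3 (232 of 932, of which 165 rose), 17.4% on chromosome 6, 15.6% on chromosome 15 and 16.5% on the others (2818 of 17069). Of these called genes, 26 of 164 rose on chromosome 6, 14 of 118 on chromosome 15 and 1255 of 2818 on the others. Most calls on chromosomes 6 and 15 were thus falls, the direction of the higher B1 and A5 control medians. The second library of line db/db 2 (a db7 line) stood apart with 4.81% of its counts on Gm42418, a transcript that overlaps ribosomal RNA sequence, against 0.123% to 0.514% in the other db/db libraries.

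**Figure D1:**
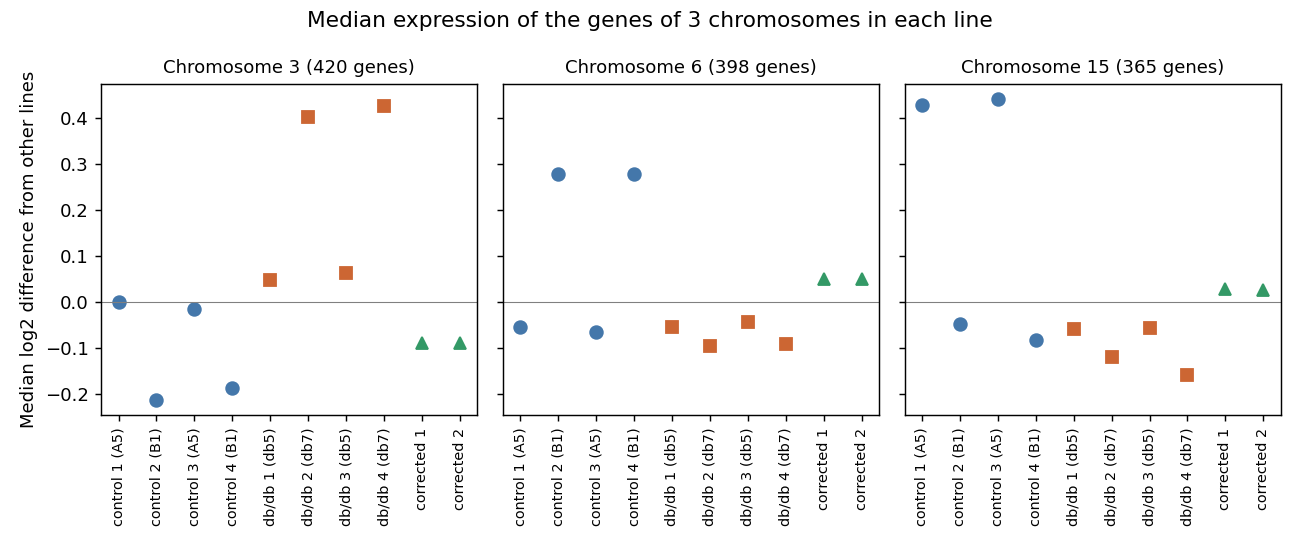
Median log2 level of the genes of chromosomes 3, 6 and 15 in each of the 10 lines (vertical axis, relative to the median of the lines of other names), with lines along the horizontal axis in the colour of their group. The db7 lines stand at 0.40 and 0.43 for chromosome 3, the A5 lines at 0.43 and 0.44 for chromosome 15 and the B1 lines at 0.28 for chromosome 6.

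Lepr itself (ENSMUSG00000057722, chromosome 4, 101717404 to 101815352, forward strand, GRCm38) was under 1 CPM in every line. Its level was 0.348, 0.431, 0.460 and 0.456 CPM in control lines 1 to 4, 0.368, 0.186, 0.371 and 0.297 CPM in db/db lines 1 to 4, and 0.718 and 0.606 CPM in the corrected lines. The difference of db/db from control lines did not pass edgeR's test (log2 -0.47 ± 0.24, Benjamini-Hochberg adjusted p = 0.2). Lepr rose in corrected against db/db lines (1.10 ± 0.27, edgeR adjusted p = 0.012), but with the shared name as the unit that call ended (edgeR adjusted p = 0.071). The db mutation changes how the transcript of the long receptor form is spliced, so a count over the whole gene does not check the genotype given in the labels.

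In db/db lines, transcripts of fibroblasts, of the two-cell-like state and of mesoderm lay below their level in control lines, and the transcripts of Stat3 and Socs3 fell. Collagen Col1a1 was at 69.3 ± 14 CPM in db/db lines and 143 ± 18 in control lines (log2 -1.04 ± 0.16), and the single gene Meg3, an imprinted long noncoding RNA, at 9.72 ± 6.1 and 58.4 ± 12 (-2.58 ± 0.42). Stat3, the transcription factor through which the long leptin receptor signals, fell from 71.6 ± 0.66 to 61.1 ± 1.8 CPM (-0.23 ± 0.05, edgeR adjusted p = 0.0091), and its target and feedback inhibitor Socs3 from 309 ± 52 to 215 ± 42 (-0.52 ± 0.15, 0.042). Of the pluripotency factors, Sox2 rose from 470 ± 36 to 658 ± 62 CPM (0.48 ± 0.08, edgeR adjusted p = 0.0038) and Nanog fell from 544 ± 80 to 410 ± 21 (-0.41 ± 0.10, 0.019). Sox2 lies on chromosome 3, which was higher in db7 lines, and Nanog on chromosome 6, which was higher in B1 control lines. With the shared name as the unit, the calls of Stat3, Socs3, Sox2 and Nanog ended, as given further on. Pou5f1 (log2 0.04), Klf4 (0.09) and Myc (0.27, on chromosome 15) did not pass edgeR's test (adjusted p = 0.59, 0.41 and 0.072). The reprogramming lentivirus also carried Oct4 (Pou5f1), Sox2, Klf4 and cMyc. In every comparison, counts of these genes were not separated into the cell's own transcripts and those of the lentivirus.

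The largest rise in db/db lines among genes named by the fixed rule was that of the noncoding transcript AA465934, from 0.732 ± 0.17 to 11 ± 0.77 CPM (3.92 ± 0.16, edgeR adjusted p = 1.8e-06). The neurofilament gene Ina (alpha-internexin) rose from 7.43 ± 0.64 to 26.8 ± 3.3 CPM (1.85 ± 0.11, edgeR adjusted p = 1.3e-05) and Wdfy1 from 8.92 ± 1.4 to 31.6 ± 3.0 (1.83 ± 0.12, 2.3e-05). The other rises were Stard9 (2.66), Obox6 (2.30), Slc40a1, which encodes the iron exporter ferroportin (2.16), Lrp2 (2.05), Stard8 (1.94), Nlrp4f (1.85) and Dok2 (1.84). Several of these rises differed between shared names of a group. Lrp2 stood at about 5 CPM in db5 lines (5.01 and 5.07) and at 20.6 and 24.96 in db7 lines. Stard8 was at 15.6 and 15.54 CPM in db5 lines, near the 13.26 and 14.27 of A5 control lines, and at 67.27 and 68.7 in db7 lines. Stard9 and Nlrp4f were also over 2-fold higher in db7 than in db5 lines on average. Obox6 was at 10.72 and 9.788 CPM in A5 and 1.495 and 1.283 in B1 control lines, and Slc40a1 and Dok2 were over 2-fold higher in A5 than in B1 lines. The largest fall was that of Rap1gap2, from 26.3 ± 13 to 1.42 ± 0.55 CPM (-4.20 ± 0.41, edgeR adjusted p = 0.00027). Next came the X-linked Xlr3c (-3.58) and Xlr5c (-2.59), Ccdc92b (-3.56), Rassf4 (-3.14) and the lysine-degrading enzyme Aass (-2.76), both on chromosome 6. The histidine-degrading enzyme Hal (-2.71) also fell, as did the noncoding RNAs Mirg (-2.91) and Rian (-2.76 ± 0.56). Among the falls, Rap1gap2, Ccdc92b, Aass and Hal were over 2-fold higher in B1 than in A5 control lines and Rassf4 over 2-fold lower, while Xlr3c, Xlr5c, Mirg and Rian were over 2-fold higher in db5 than in db7 lines. An unnamed gene identifier, ENSMUSG00000107391, carried the same values as Rian. The Xlr3 and Xlr5 genes are families of near copies, so reads may have been divided among members and their values are uncertain. The rule left out 5 rises and 6 falls of predicted genes and pseudogenes of this size.

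Of 41 tested fibroblast genes, 23 fell and 0 rose (29 fell when adjusted over the list alone), with a median log2 of -0.69. Col5a1 went from 64.6 ± 6.3 to 36.4 ± 1.2 CPM (-0.83 ± 0.07) and the matrix gene Fbln2, on chromosome 6, from 72.8 ± 5.8 to 45.5 ± 2.3 (-0.68 ± 0.08). The fibroblast medians of single lines, relative to the control mean, were -0.93 in both db5 lines, -0.46 and -0.47 in the db7 lines, and 0.04 and -0.24 in the corrected lines. Of 25 genes of the two-cell-like state, a rare state of pluripotent cultures that resembles the two-cell embryo, 20 fell and 0 rose (21 fell adjusted over the list alone; median -1.78). The medians of single lines, relative to the control mean, were -1.2 and -1.3 in the db5 lines and -2.3 and -2.5 in the db7 lines, so the median between these names was -1.3 against -1.83 between genotypes. Among them, Zscan4f fell from 9.14 ± 1.9 to 1.81 ± 0.99 CPM (-2.33 ± 0.36) and Duxf3 from 0.831 ± 0.25 to 0.205 ± 0.054 (-2.0 ± 0.30). Zscan4, Usp17l and Gm12794 belong to families of near copies, so their single values are uncertain. Camera with a preset correlation gave an adjusted p of 9.08e-11 for each of these lists, and adjusted p = 0.578 with an estimated correlation.

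Of 33 mesoderm genes 7 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.00501). Gata6 fell from 1.93 ± 0.78 to 0.480 ± 0.14 CPM (-2.01 ± 0.33) and Snai1 from 3.11 ± 0.30 to 1.82 ± 0.28 (-0.77 ± 0.15). Of 16 immediate early genes, which respond within minutes to growth signals, 7 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.0144). Atf3 fell from 18.4 ± 3.1 to 6.28 ± 1.2 CPM (-1.55 ± 0.16) and Fos from 384 ± 51 to 254 ± 18 (-0.60 ± 0.09), while Klf6 rose (0.41 ± 0.07). Of 37 imprinted genes, which are expressed from the allele of a given parent, 10 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.0358). Plagl1 fell from 23.9 ± 1.6 to 10.8 ± 2.4 CPM (-1.14 ± 0.14) and Impact rose (0.43 ± 0.08). For all 3 lists adjusted p = 0.578 with an estimated correlation.

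The lists that rose were mTOR pathway components, with 7 of 44 genes up and 1 down (12 and 1 adjusted over the list alone; camera adjusted p = 0.0316), and primed pluripotency, with 8 of 17 up and 1 down (9 and 2 adjusted over the list alone; camera adjusted p = 0.0406). Both had adjusted p = 0.578 with an estimated correlation. The ribosomal S6 kinase gene Rps6ka3, on the X chromosome, rose from 23.3 ± 0.32 to 42.0 ± 4.9 CPM (0.85 ± 0.08). Lamtor3, on chromosome 3, rose from 39.4 ± 4.4 to 67.6 ± 9.3 (0.78 ± 0.11), and Rragb, on the X chromosome, from 2.06 ± 0.76 to 5.69 ± 1.3 (1.48 ± 0.27). The median of X-chromosome genes was higher in every db/db line than in every control line, but by less than the rises of Rps6ka3 and Rragb. Corrected lines, in which Rragb fell, had X medians of 0.065 and 0.064. The X median therefore does not account for these 2 rises, and whether they are particular to the pathway was not tested. Of the genes of the primed state, which follows implantation, Lef1 (1.32 ± 0.26, on chromosome 3), Fst (0.50 ± 0.09) and Zic2 (0.29 ± 0.07) rose and Cdh2 fell (-0.65 ± 0.16).

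Lists of the protein synthesis machinery did not pass the test between db/db and control lines. Of 81 cytosolic ribosomal protein genes 1 rose and 2 fell (0 adjusted over the list alone; camera adjusted p = 0.224), of 77 mitochondrial ribosomal protein genes 3 rose and 1 fell (0 adjusted over the list alone; 0.988), and of 70 ribosome biogenesis factors 6 rose and 2 fell (0 adjusted over the list alone; 0.283). Camera's adjusted p was 0.243 for translation initiation factors (3 of 43 rose and 2 fell, as when adjusted over the list alone), 0.647 for elongation and termination factors (0 of 17 called) and 0.647 for aminoacyl-tRNA synthetases (1 of 21 rose and 2 fell, as when adjusted over the list alone). The cap-binding factor Eif4e, on chromosome 3, rose from 236 ± 34 to 406 ± 71 CPM (0.78 ± 0.13), and Eif1ax, on the X chromosome, from 87.5 ± 2.0 to 189 ± 20 (1.11 ± 0.07). In neuron genes, 4 of 46 rose and 11 fell (7 and 16 adjusted over the list alone; camera adjusted p = 0.109). Besides Ina, Nefl rose from 27.5 ± 1.8 to 50.7 ± 9.2 CPM (0.88 ± 0.12), and Gap43 (-1.90 ± 0.25) and Slc32a1 (-2.55 ± 0.35) fell at levels under 3 CPM. Of 34 neural progenitor genes 5 rose and 6 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.854), with Pax6 (1.32 ± 0.20) and Gbx2 (0.61 ± 0.07) up and Nes, on chromosome 3, down (-0.94 ± 0.16). Of 28 genes of the leptin receptor and JAK-STAT3 pathway 4 rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.393).

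In all, 3332 of 19700 genes (16.9%) passed edgeR's test between db/db and control lines, with 1460 up and 1872 down, and 1165 of them changed at least 2-fold (292 up and 873 down). With library size alone as the scaling the split was 1085 up and 2156 down. With shared names as the unit (2 against 2) edgeR called 6 genes, of which AA465934 is the named example (edgeR adjusted p = 0.035), and the other 19 genes of largest change had adjusted p-values of 0.21 to 0.47. The calls of Stat3, Socs3, Sox2 and Nanog ended as well (edgeR adjusted p = 0.59, 0.52, 0.4 and 0.47). In that fit 2030 of the 20173 genes outside a window of 200 genes around Lepr (10.1%) had an unadjusted edgeR p under 0.05. Camera with shared names as the unit called 4 lists, the fibroblast, two-cell-like and mesoderm lists down and replication-dependent histones up (median 1.15, adjusted p = 0.000118), of which 1 of 21 rose in the line-level test (0 adjusted over the list alone; camera adjusted p = 0.109). With an estimated correlation, which was 0.481 for the histone list, its line-level adjusted p was 0.786 by camera, and fry gave 0.372. The calls of the mTOR, immediate early, imprinted and primed lists ended (camera adjusted p = 0.0616, 0.0616, 0.0658 and 0.0667). With shared names in 3 groups of 2, camera called 6 lists, since the mTOR and immediate early lists kept their call (adjusted p = 0.0469 and 0.0341). Without control line 2 or control line 4 the count of genes at the level of lines was 1991 or 2021.

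**Figure D2:**
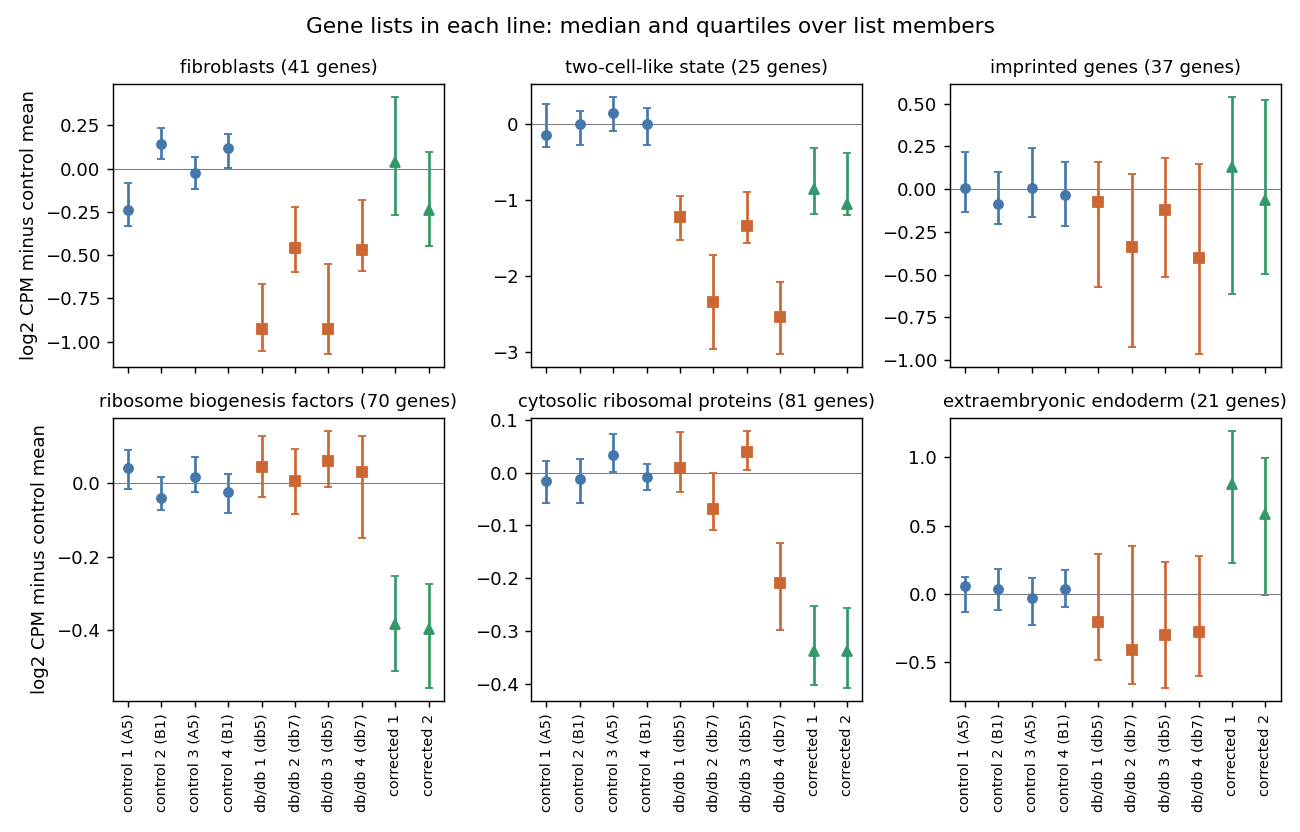
Median log2 level of the members of 6 gene lists in each of the 10 lines, relative to the control mean (vertical axis), with bars from the lower to the upper quartile of the members and colours for the groups. The fibroblast medians of the db/db lines lie between -0.93 and -0.46, and the ribosome biogenesis medians of the corrected lines at -0.38 and -0.40 against 0.01 to 0.06 in db/db lines.

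In corrected lines, transcripts for building and running ribosomes lay below their level in db/db lines, and those of extraembryonic endoderm above it. Of 70 ribosome biogenesis factors 57 fell and 0 rose (58 and 1 adjusted over the list alone), with a median log2 of -0.39. Nop58, a core protein of small nucleolar particles, fell from 449 ± 15 to 260 ± 4.6 CPM (-0.79 ± 0.06, edgeR adjusted p = 3.2e-05). Of 81 cytosolic ribosomal protein genes 55 fell (60 adjusted over the list alone; median -0.30), such as Rpl35 from 369 ± 25 to 254 ± 2.5 CPM (-0.54 ± 0.07), and of 77 mitochondrial ribosomal protein genes 47 fell (56 adjusted over the list alone; median -0.35). The cytosolic ribosomal medians of single lines, relative to the control mean, were -0.34 in both corrected lines, -0.21 in db/db line 4 and between -0.07 and 0.04 in the other db/db lines. Of 21 aminoacyl-tRNA synthetases 16 fell (18 adjusted over the list alone), with Aars down from 429 ± 14 to 240 ± 6.0 CPM (-0.84 ± 0.07) and Rars from 201 ± 2.3 to 124 ± 0.27 (-0.70 ± 0.06). Camera's adjusted p-values were 9.01e-17, 5.95e-11, 2e-11 and 4.02e-08 for these 4 lists. In the same order, adjusted p = 0.181, 0.444, 0.379 and 0.379 with an estimated correlation.

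Of 43 initiation factors 22 fell and 1 rose (24 and 1 adjusted over the list alone; camera adjusted p = 9.43e-06), with Eif4e, on chromosome 3, down from 406 ± 71 to 167 ± 0.90 CPM (-1.28 ± 0.17) and Eif4a2 up (0.62 ± 0.08). Of 17 elongation and termination factors 10 fell (11 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00126). Of 34 ATF4 target genes, the amino acid response, 19 fell and 3 rose (21 and 4 adjusted over the list alone; camera adjusted p = 5.1e-05), and the proline synthesis enzyme Aldh18a1 fell from 96.2 ± 3.6 to 41.6 ± 0.70 CPM (-1.21 ± 0.06). Of 44 mTOR pathway components 19 fell and 5 rose (21 and 5 adjusted over the list alone; camera adjusted p = 0.0019), among them Rragc from 81.3 ± 2.7 to 44.2 ± 0.17 CPM (-0.88 ± 0.07). Nuclear genes of oxidative phosphorylation fell in 42 of 74 (47 fell and 1 rose adjusted over the list alone; camera adjusted p = 5.14e-09), cholesterol synthesis genes in 11 of 24 (11 adjusted over the list alone; 6.33e-05) and S phase genes in 15 of 27 (15 adjusted over the list alone; 0.000211). With an estimated correlation, adjusted p = 0.379 for the initiation, mTOR, cholesterol and S phase lists and adjusted p = 0.444 for the elongation, ATF4 and oxidative phosphorylation lists.

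Of 21 extraembryonic endoderm genes 15 rose and 1 fell (15 and 3 adjusted over the list alone; camera adjusted p = 0.000236; adjusted p = 0.222 with an estimated correlation). The type IV collagens Col4a1, from 64.5 ± 9.4 to 172 ± 6.8 CPM, and Col4a2, from 35.3 ± 2.8 to 94.0 ± 3.4, both rose by 1.41 on the log2 scale. Of 33 mesoderm genes 15 rose and 1 fell (18 and 2 adjusted over the list alone; camera adjusted p = 0.000609; adjusted p = 0.379 with an estimated correlation), most of them at low levels, such as Pdgfra from 0.942 ± 0.054 to 2.86 ± 0.41 CPM. Of 41 fibroblast genes 18 rose and 0 fell (19 and 1 adjusted over the list alone; camera adjusted p = 0.00136; adjusted p = 0.582 with an estimated correlation), with Col5a1 up from 36.4 ± 1.2 to 83.0 ± 3.9 CPM (1.19 ± 0.09). Of 25 two-cell-like genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0102; adjusted p = 0.6 with an estimated correlation). The two-cell-like median of the corrected lines lay 1.62 above the db7 lines and 0.30 above the db5 lines. The other called lists had camera adjusted p-values of 0.01 to 0.0296, and adjusted p = 0.379 to 0.6 with an estimated correlation. Glia genes rose in 5 of 11 (5 adjusted over the list alone), and blood cell genes rose in 5 of 11 and fell in 1 (6 and 1 adjusted over the list alone). ERK target genes fell in 8 of 22 and rose in 2 (9 and 2 adjusted over the list alone), lysosome genes fell in 11 of 32 and rose in 3 (12 and 3), and mitochondrially encoded genes fell in 3 of 13 (3). Neuron genes went both ways, with 12 of 46 up and 10 down (12 and 12 adjusted over the list alone; camera adjusted p = 0.781). Ina fell from 26.8 ± 3.3 to 3.87 ± 0.26 CPM and the glutamate receptor gene Grin1 from 16.3 ± 4.9 to 3.44 ± 0.21.

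The largest single rises in corrected lines were Zan (3.98 ± 0.44), Gprc5c, from 0.952 ± 0.14 to 14.1 ± 0.16 CPM (3.89 ± 0.16, edgeR adjusted p = 5.6e-06), and the glutamate transporter Slc1a1 (3.62). Next came Pramel6 (3.32), Cd200 (3.27), Calcoco2 (3.13) and the imprinted growth factor Igf2, from 3.0 ± 0.41 to 24.3 ± 2.5 CPM (3.02 ± 0.24, edgeR adjusted p = 4.6e-05). Ptges (3.02), Gata3 (2.96) and Cited4 (2.94) followed. The largest falls were the connexin gene Gjb1, from 16.3 ± 4.0 to 1.61 ± 0.38 CPM (-3.34 ± 0.30, edgeR adjusted p = 8.4e-05), Pde5a (-2.92, on chromosome 3) and Ina (-2.79). Smaller falls were those of Armcx2 and Bcl11a (both -2.59), Lrp8os2 (-2.53), Ndufa4l2 (-2.45), the Nodal antagonist Lefty1, from 87.1 ± 53 to 16.5 ± 1.9 (-2.40 ± 0.55), Rragb and Tbc1d9 (both -2.37). Pde5a stood at 3.81 and 3.32 CPM in db5 lines and at 25.2 and 27.5 in db7 lines. Stat3 fell from 61.1 ± 1.8 to 39.1 ± 0.79 CPM (-0.64 ± 0.06, edgeR adjusted p = 8.2e-05) and Socs3 by -0.77 ± 0.19 (0.012). Myc fell from 724 ± 97 to 389 ± 11 (-0.90 ± 0.12, edgeR adjusted p = 0.00051), Sox2 by -0.71 ± 0.10 (0.00068) and Pou5f1 by -0.25 ± 0.06 (0.0086), while Nanog rose (0.42 ± 0.11, 0.018). The rule left out 3 rises and 1 fall of predicted genes.

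Between corrected and db/db lines 7235 genes (36.7%) passed edgeR's test, with 3683 up and 3552 down. Of these, 1856 rose and 633 fell at least 2-fold. With library size alone as the scaling the median of all genes lay at 0.19 (ribosome biogenesis at -0.22), with 5215 genes up and 1817 down. Without corrected line 1 or 2 the counts were 3113 and 3183. With shared names as the unit edgeR called 3281 genes when the corrected lines were kept apart. The calls of Pramel6, Pde5a, Tbc1d9, Socs3, Pou5f1 and Nanog then ended (edgeR adjusted p = 0.064, 0.077, 0.062, 0.053, 0.073 and 0.084). With the near-identical corrected lines as 1 sample edgeR called 0 genes, while 3833 of 22352 had an unadjusted p under 0.05 and limma-voom with the shared name as a block called 3760.

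Corrected lines also differed from control lines, again with less ribosome-related transcript. Of 81 cytosolic ribosomal protein genes 66 fell and 0 rose (72 adjusted over the list alone; median -0.34; camera adjusted p = 9.2e-14), of 70 ribosome biogenesis factors 56 fell (57 and 1 up adjusted over the list alone; 1.63e-15) and of 77 mitochondrial ribosomal protein genes 49 fell (60 adjusted over the list alone; 2.8e-12). With an estimated correlation these had adjusted p = 0.513, 0.222 and 0.513. Of 34 ATF4 target genes 19 fell (21 adjusted over the list alone; camera adjusted p = 8.17e-07; adjusted p = 0.513 with an estimated correlation), and Aldh18a1 fell from 119 ± 3.6 to 41.6 ± 0.70 CPM (-1.52 ± 0.06). Stat3 fell from 71.6 ± 0.66 to 39.1 ± 0.79 CPM (-0.87 ± 0.06, edgeR adjusted p = 2.7e-05), and Socs3 from 309 ± 52 to 126 ± 4.2 (-1.30 ± 0.20, 0.0013). Sox2 (-0.22 ± 0.10) and Nanog (0.01 ± 0.12) did not pass edgeR's test (adjusted p = 0.1 and 0.96), and Myc fell (-0.62 ± 0.12, 0.0034).

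Fibroblast genes did not pass as a list between corrected and control lines (4 of 41 rose and 5 fell, as when adjusted over the list alone; camera adjusted p = 0.403), and two-cell-like genes fell in 6 of 25 (3 adjusted over the list alone; camera adjusted p = 0.00378; adjusted p = 0.678 with an estimated correlation). Extraembryonic endoderm genes rose in 11 of 21 and fell in 2 (12 and 3 adjusted over the list alone; camera adjusted p = 0.00178; adjusted p = 0.405 with an estimated correlation). The remaining called lists were down, and all had adjusted p = 0.513 with an estimated correlation. Oxidative phosphorylation genes fell in 43 of 74 (51 adjusted over the list alone; camera adjusted p = 1.19e-09) and aminoacyl-tRNA synthetases in 17 of 21 (18 adjusted over the list alone; 1.44e-08). Cholesterol synthesis genes fell in 13 of 24 and rose in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 0.000536). Initiation factors fell in 25 of 43 and rose in 3 (27 and 3; 0.00116), S phase genes fell in 11 of 27 and rose in 1 (12 and 1; 0.00168), and elongation and termination factors fell in 10 of 17 (11 and 1 up; 0.00378). Neuron genes did not pass as a list (8 of 46 rose and 11 fell; 8 and 12 adjusted over the list alone; camera adjusted p = 0.397), although the neuronal tubulin Tubb3 fell from 65.8 ± 18 to 12.6 ± 0.64 CPM (-2.39 ± 0.30).

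The largest rises against control lines were Cd200, from 0.878 ± 0.11 to 16.2 ± 0.36 CPM (4.2 ± 0.48, edgeR adjusted p = 0.00032), Slamf6 (3.82), AA465934 (3.75), Mmp12 (3.68) and Obox6 (3.10). Next came Cachd1, from 6.32 ± 2.9 to 50.5 ± 0.74 CPM (3.01 ± 0.32), Ugt1a6b (3.0), Clec2g (2.95, on chromosome 6), Nlrp4f (2.79) and Rin3 (2.76). The largest falls were Rap1gap2 (-3.51), Ccdc7a (-3.30), Lefty1, from 155 ± 31 to 16.5 ± 1.9 CPM (-3.23 ± 0.57), Ccdc92b (-3.05) and Lexm (-2.98). Smaller falls were those of the glycogen enzyme Pgm1, from 28.9 ± 6.6 to 3.76 ± 0.14 (-2.94 ± 0.28), Slfn9 (-2.66), Clca3b (-2.57, on chromosome 3) and Lrp8os2 (-2.53). Cachd1, Pgm1, Lexm and Lrp8os2 lie on chromosome 4 in the window of 200 genes around Lepr described further on. Lrp8os2 is annotated as antisense, and whether counting used the strand is not given in the sources used here. An unnamed identifier, ENSMUSG00000116466, carried the same values as Pgm1. The rule left out 7 rises and 8 falls of predicted genes and pseudogenes.

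In all, 6537 genes (33.2%) passed edgeR's test between corrected and control lines, 3184 up and 3353 down. At least 2-fold, 1357 rose and 721 fell. With library size alone as the scaling the median of all genes lay at 0.12, with 4407 genes up and 2049 down. Without corrected line 1 or 2 the counts were 2438 and 2377. With shared names as the unit edgeR called 2547 genes, and the calls of Obox6, Ccdc7a, Lexm and Pou5f1 ended (edgeR adjusted p = 0.061, 0.053, 0.067 and 0.11). It called 4 genes with the corrected lines as 1 sample.

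The design also asks whether correction brought back the differences of db/db lines. Of the 3332 genes called between db/db and control lines, 1515 (45.5%) changed back in corrected lines, 639 that had risen and 876 that had fallen, while 226 (6.8%) changed further the same way. Meg3 was at 46.3 to 71.2 CPM in control lines, 4.09 to 15.2 in db/db lines, and 37.6 and 41.03 in corrected lines, and Rian at 29.5 to 33.5, 1.24 to 7.95, and 19.5 and 20.6. AA465934 and Rap1gap2 stayed near the db/db level. Because db/db lines enter both comparisons, part of such a count comes with no effect at all. In 20 simulated data sets of unchanged groups the median was 0 genes with independent lines and 372 (at most 418) with lines of a shared name as alike as here, and independent lists of these sizes would share 613. Simulated genes varied independently of each other, so these counts do not cover genes that move together between lines. Across genes, which are not independent replicates, the log2 changes had a correlation of -0.402 and a covariance of -0.238, against -0.404 and -0.092 in the simulated unchanged groups with alike lines.

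With separate db/db lines on each side, db5 against control and corrected against db7, 1587 genes changed back and 490 changed further (728 back for independent lists, covariance -0.175). With the names exchanged 1776 changed back and 1425 further (1386 back for independent lists, covariance -0.089). With shared names as the unit 12 genes changed back. Without a line the count was 907 (control line 2), 934 (control line 4), 997 (db/db line 2), 661 or 685 (corrected line 1 or 2). On an axis from 0 (control) to 1 (db/db), with each line placed by genes chosen without it, corrected lines lay at 0.511 ± 0.011, between control lines at 0.072 ± 0.101 and db/db lines at 0.939 ± 0.139. An exact permutation test (two-sided) gave p = 0.067 against either group, the smallest p that 4 lines against 2 allow. With both lines of a name held out the positions were 0.425, 0.333 and 0.669, and the exact permutation p was 0.133 against db/db and 0.467 against control lines.

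Around Lepr, 50 of the 200 tested genes nearest to it (25%) changed between db/db and control lines, against 16.8% of the others (3282 of 19499). The odds ratio was 1.65 (95% interval 1.17 to 2.29, Fisher's exact p = 0.00321, two-sided) over chromosome 4 from 70248636 to 116097043 (GRCm38). The called genes there include Skint8 (-0.89), Eps15 (0.40), Efcab7 (1.09), Mknk1 (-0.35) and Faah (-0.94), named after their values were seen. They also include predicted genes on both sides of Lepr, such as Gm11487 (-2.0) and Gm12790 (-1.80), which belong to families of near copies that can share reads. Without predicted genes and pseudogenes the window was refilled to 200 genes and so reached further, from 59471868 to 116805956. The share there was 43 of 200 (21.5%) against 17.9%, and the odds ratio of 1.26 did not pass (0.87 to 1.77, Fisher's exact p = 0.194). Of the 50 called genes, 12 (24%) changed back in corrected lines, against 45.8% of the other called genes (odds ratio 0.37, Fisher's exact p = 0.00234).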

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

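Of the tests in this part, those of chromosome copy number, of transcript length and GC content, of scaling between libraries, and of lines of the same genotype for the ribosomal protein lists were chosen only after the result was seen. The readings of the tests of splits, of shared names and of the duplicate number were also set after their values were known.

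Of 137 groups of values checked for a library or line far from the rest, 4 stood out, and chance alone gives about 1 in 20. The second library of line db/db 2 had 4.81% of its counts on Gm42418 (0.123% to 0.514% in the other db/db libraries) and 1.786% on Lars2 (0.197% to 0.365%). AA465934 was at 9.81 CPM in line db/db 1 and at 11.3 to 11.4 in the other db/db lines. Clec2g was at 1.78 CPM in control line 3 and at 1.28 to 1.34 in the other control lines.

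Of the 35 splits of the 8 lines into groups of 4, only 3 keep near-copy lines of a shared name together, too few for a share under 0.05: 1 of the 3, the real one, reached the 3332 called genes between db/db and control lines, and the highest other called 579. On the other chromosomes 16.5% of tested genes were called, which argues against the direct dosage of genes on chromosomes 3, 6 and 15 as the whole cause. Whether a difference in copy number altered genes elsewhere was not tested. Each control line stood high on chromosome 15 (A5, 0.43 and 0.44) or chromosome 6 (B1, 0.28), and the db5 lines on neither. Such an influence therefore cannot be told apart from the group. That lines of a shared name were counted as independent samples stays open: the mixed splits that keep names together called 481 and 579 genes, at most 17.4% of the real count, below the bound set beforehand for this cause. That bound was wrong, because simulated unchanged groups with lines as alike as these gave 1407 to 1727 calls. The real count of 3332 lay above that range of 20 simulated sets, which concerns the count and not which genes. Genes varied independently of each other in the simulation, while real lines differed over whole chromosomes. The mixed splits, at 481 and 579, lay below the range. It is therefore no limit for a count without an effect of genotype. Shared names as the unit left 6 genes. For most called genes, differences of genotype and differences between the founding clones therefore cannot be told apart with 2 names a group. The effect of the db mutation, of the embryo from which a line came and of its reprogramming each stay among the open explanations.

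In the lower fibroblast list of db/db lines, 38 of 41 members lay below 0 (92.7%). The 10 most abundant members all moved down, from -1.04 for Col1a1 to -0.11 for Fn1, a range of 0.93. Those values met the bounds set beforehand for a larger share of fibroblasts in the control libraries. They do not establish it, since the falls were unequal in size and 3 members lay above 0. These were Thbs2 (0.02), Fap (0.31) and Dcn (0.82). Fap was at 0.355 CPM in control and 0.453 in db/db lines, and Dcn at 0.11 and 0.191. Fn1 stood at 1130 CPM in control and 1050 in db/db lines, Vim at 165 and 139 and Col1a2 at 78.5 and 43.0; 24 of the 41 members were at 5 CPM or more in db/db lines too, and 4 are held by another list. The duplicate numbers are spread almost evenly over the groups, so the list's median of -0.75 with that number as a block was no test of them. Differences between lines of the same genotype cannot be told apart from the genotype with 2 names a group, since the medians between names were as large as 0.44 (db7 above db5) against -0.70 between genotypes. A residual of the starting fibroblasts, feeder cells, of which the labels say nothing, and a change of the pluripotent cells themselves may each be the source.

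The protein synthesis lists were lower in corrected than in db/db lines. With a trend over transcript length and GC content removed, the highest adjusted p of the 3 lists was 6.86e-10 by camera, which argues against that trend as the whole cause. A scaling factor moves all genes alike, so the ribosome biogenesis median lay -0.41 from that of all genes without factors as with them, which is no test of scaling, and it stays open for the level itself. Differences between names of the same genotype were at most 0.07 in size for the ribosome biogenesis list and 0.13 for the mitochondrial ribosomal list, against -0.39 and -0.35 for corrected minus db/db lines, but reached 0.16 for the cytosolic ribosomal list against -0.29, where both cannot be told apart with 2 names a group. Control lines, which lack the mutation, lay near the db/db lines. For the ribosome biogenesis, mitochondrial and cytosolic ribosomal lists, db/db minus control was 0.02, -0.01 and -0.06. Corrected minus control was -0.39, -0.38 and -0.34. These values argue against a return to the control level as the cause, for these 3 lists. An effect of the correction of Lepr other than such a return and growth of the cells at harvest remain as hypotheses. So does the single lineage to which both corrected lines appear to belong. Separate handling of the corrected libraries cannot be told apart from the correction either. Without corrected clones of separate origin, none of these was tested against the others.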

How the results depend on the processing

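Of the alternatives in this part, those with shared names as the unit in all comparisons or as a block, without a shared name, without predicted genes, and with library size alone, and for the gene lists also shared names as the unit (2 against 2) and the fits of single libraries with and without the duplicate number as a block, were chosen only after the data were seen; the cause of a difference was not tested except where fewer samples or genes entered. Over all named genes and settings 14908 values kept their direction and side of the threshold, 1841 lost the call, 200 gained it and 1 turned: Hspa8 in corrected against db/db lines, at 0.01 with library size alone. Over lists 2899 stayed, 54 lost the call, 77 gained it and 0 turned, without counting 2 settings of the list test itself: camera with an estimated correlation, which ended all list calls (7, 20 and 12), and fry. Counts of genes within 1.5 times are given as a range: RLE, upper-quartile and library size scaling gave 3241 to 3379, 7032 to 7336 and 6456 to 6593 genes for db/db against control, corrected against db/db and corrected against control.

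For db/db against control, the count of 3332 became 7247 with each library as a sample, 2155 with at least 5 CPM, 2385 in a fit of only control and db/db lines and 1439 in that fit with the first letter of the name as a covariate, 5397 without both A5 lines and 5410 without both db5 lines. The duplicate number pairs the libraries, and with it as a replicate block 6188 genes were called against 6175 without the block in the same fit of single libraries, with 6 lists called by each fit. Shared names as the unit gave 6 genes (2 against 2), 34 (3 groups of 2) and 6 (corrected lines as 1), and 1389 as a random block. For corrected against db/db, shared names gave 3281, 0 and, as a block, 3760 genes; for corrected against control 2547, 4 and 3269. Leaving out a line gave 1991 to 3211 (1991 and 2021 without control line 2 and 4), 3113 to 7638 and 2377 to 7236 genes, with the lowest of each of the last pair without a corrected line. The count of genes changed back was 999 with at least 5 CPM and 12 with shared names, and 661 to 1477 without a line.

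Lists called between db/db and control lines numbered 0 with an estimated correlation, 18 by fry, 4 with shared names (2 against 2), 6 with shared names (3 groups of 2) and 16 without both db7 lines, and 5 to 9 without a line. For corrected against db/db these were 0 and 31 (18 to 24 without a line), and for corrected against control 0 and 29 (12 to 13). The odds ratio near Lepr was 1.26 without predicted genes and pseudogenes, in a wider window refilled to 200 genes. Whether depth limits the counts was not tested; Lepr lay under 1 CPM in every line. DESeq2 called 4730, 7995 and 7411 genes, and made 42 false calls of 137 on simulated data with independent lines for db/db against control.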

Other observations

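Of the tests in this part, that of variants between the parental genomes was chosen only after the result was seen, and the splits of the genes near Lepr were set aside as too few after it was seen that most call no gene.

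The imprinted genes Igf2 and H19, neighbours on chromosome 7, were highest in corrected lines. Igf2 was at 3.82 to 6.89 CPM in control lines, 2.61 to 3.49 in db/db lines, and 26.1 and 22.6 in corrected lines, and H19 at 17.4 to 20.3, 6.95 to 13.1, and 42.1 and 36.2. Between corrected and db/db lines 14 of 37 imprinted genes rose and 5 fell (15 and 6 adjusted over the list alone), which did not pass as a list (camera adjusted p = 0.0939). Plagl1 rose from 10.8 ± 2.4 to 26.7 ± 0.64 CPM and Impact fell from 253 ± 18 to 131 ± 3.5. Lefty1 differed within db/db lines, at 133 CPM in db5 lines and 43.2 and 38.5 in db7 lines.

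Fosb was at 191 ± 9.8 CPM in control and 62.7 ± 4.7 in corrected lines (-1.61 ± 0.23), and Ier2 at 222 ± 11 and 141 ± 3.0 (-0.65 ± 0.08), while Nr4a2 rose from 1.38 ± 0.054 to 3.70 ± 0.079 (1.42 ± 0.18). Of 16 immediate early genes 7 fell and 3 rose in that comparison, as when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.108; 0.617 with an estimated correlation).

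The 7 lists called between db/db and control lines were no more than many other groupings gave: 17 of the 35 splits of the 8 lines called as many, and the highest other called 18, so chance cannot be excluded for the number of lists. Near Lepr, the odds ratio of 1.65 was the highest of the 3 splits that call any gene (highest other 1.24), too few for a share under 0.05.

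A candidate explanation for the called genes near Lepr is alleles of another strain that stayed beside the db mutation, which correction of the mutation alone would leave in place. Of the called genes near Lepr 24% changed back in corrected lines, against 45.8% of the others (Fisher's exact p = 0.00234). Without predicted genes and pseudogenes the excess of calls did not pass, but in a wider window, refilled with genes further from Lepr. That result cannot decide between this explanation and read sharing within the gene families there, and they cannot be told apart. The called genes there also include Gm12794 (-2.07), named above with the two-cell-like genes. Whether the fall of that list added to the excess was not tested.

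Of 74 genes that changed at least 8-fold between db/db and control lines, 31.1% were annotated pseudogenes, against 6.9% of all tested genes (odds ratio 6.2, Fisher's exact p = 4.61e-10). Gm4322, a processed pseudogene, was at 18.0 ± 0.88 CPM in control lines, 0.0198 ± 0.0094 in db/db lines and 0.00722 ± 0.01 in corrected lines, and Tdgf1-ps1 at 22.2 ± 1.8, 0.141 ± 0.061 and 0.202 ± 0.082. Such near on or off values that stay in corrected lines are consistent with variants that separate the parental genomes, which move reads between a gene and its processed copies. Not all members of the set stayed: the pseudogene Gm8038 was at 1.66 ± 0.51, 0.184 ± 0.038 and 1.04 ± 0.36 CPM in control, db/db and corrected lines. Control lines differed among themselves in Gm12191, at 121 ± 140 CPM. The 74 genes were not matched to all tested genes for level, so the share of pseudogenes was not separated from low counts. No sequence was analysed here, and a change of transcription was not excluded.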
